A study of Homo sapiens with 6 samples.

How the data were processed

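SUM149PT cells, an established line of triple-negative inflammatory breast cancer, were reverse-transfected with siRNA in 384-well plates and then left untreated or given eicosapentaenoic acid (EPA), a polyunsaturated fatty acid. Per the labels' protocols, siRNA at 45 nM was complexed with a transfection reagent for 30 minutes, 750 cells were added per condition, and the plates stood for 48 hours. EPA at 50 µM, a dose the labels call an IC50, followed for a further 72 hours. Cells were then incubated with a resazurin reagent, which living cells reduce to a fluorescent product, and the fluorescence intensity of each well was read on a plate reader. There were 3 untreated and 3 EPA-treated samples. No source used here says whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

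The values deposited by the authors are raw fluorescence intensity, 1 value per well and sample, per the file headers. Blank subtraction, position correction and normalization by the authors are not given in the sources used here, and the blank wells still carry signal in the deposited values. The columns of the deposited table are headed by group and numbered 1 to 6 through both groups, so a column could be assigned to a group but not to a numbered sample of the labels. The columns are called untreated replicates 1 to 3 and EPA-treated replicates 4 to 6 here. All 6 columns were used.

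The table held 1152 wells on 3 plate layouts of 16 rows and 24 columns. The 939 library wells carried 779 siRNAs of a kinome library and 160 of a GPCR library, with 926 distinct catalogue numbers, 13 of them on 2 wells. Each plate also had 16 blank wells, 24 wells of cells alone, 16 wells of OTP3, which the labels name as the negative siRNA control, and 8 wells of TOX, the positive one. The labels do not spell out either abbreviation. A further 21 wells marked as having no siRNA entered no fit. Gene symbols were updated through the locus identifiers in the file and a RefSeq gene table of assembly GRCh38.p14. Of the 939 library wells, 933 matched, and 188 had a symbol that differs from the current one. One well whose locus identifier belongs to FYN carries the symbol and transcript of LYN and was taken as LYN. The library reagents' sequences were not used here.

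The tests, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. Fluorescence was divided by the median of the library wells of the same plate and sample and put on a log2 scale, with no pseudocount and no filter on low values. limma 3.58.1 in R 4.3.3 fitted a mean per group to the 939 library wells over all 6 samples, with moderated variances (trend and robust options). It tested 3 contrasts: the untreated mean against 0, the EPA-treated mean against 0, and EPA-treated minus untreated, the synthetic lethal comparison. A negative value in the last contrast means a lower signal with EPA, relative to the plate, than without it. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Single quantities were compared by an exact permutation test, which for 3 samples against 3 cannot go below p = 0.1. The precision is limited by 3 samples per group and by the distance of each well from the blank level. The separation of OTP3 from TOX is given as the Z′ factor, which is 1 minus 3 times the summed SDs over the difference of the means.

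The named genes are, in each contrast, the 12 lowest and 8 highest siRNAs past the threshold with the same sign in every replicate, or, for EPA-treated minus untreated, with no overlap between the groups. Sign and overlap were judged on the log2 values relative to the plate's library median. Some of the genes and lists these rules select are not reported here. With fewer than 5 passing in a direction, the 5 most extreme would have been given as values. The controls, EPHA2 and the other Eph receptors were always named, as were 2 to 4 members with the largest moderated statistic in each gene list described. Of 27 gene lists with 421 genes, 388 genes were measured. The 26 lists with at least 3 measured members were tested with camera, at a preset correlation of 0.01 and with an estimated one, and with fry.

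The fit was tested on simulated data made from the spread of these 939 siRNAs. For EPA-treated minus untreated it recovered 97.5% of simulated differences of -1.5 and 92.5% of those of -1 on the log2 scale, but 45% of those of -0.5, and 10 of 163 calls (6.13%) were unchanged siRNAs. The simulation had no plate position effect and no blank level.

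Alternatives covered centring on OTP3, blank subtraction with a floor of 3 SDs of the blank wells, a linear scale, robust z-scores, quantile normalization, a low-signal filter at 2 times the TOX mean, variance models, thresholds, median polish of plate rows and columns, and leaving out each replicate. Chosen after seeing the data were blank subtraction together with median polish, leaving out plate rows 1 and 16 and column 24, leaving out plate 3 of untreated replicate 1, a filter on the TOX median, median polish for the gene lists, and centring EPA-treated minus untreated on its own plate median. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.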

Results

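The screen measured the fluorescence of SUM149PT cells under each of 939 library siRNAs, in 3 untreated and 3 EPA-treated samples. The purpose named for the series was to find a druggable target whose loss adds to the effect of EPA on these cells. Replicates ranked the siRNAs alike. Across siRNAs, which are not independent replicates, log2 fluorescence correlated with r from 0.897 to 0.919 among untreated replicates, from 0.908 to 0.942 among EPA-treated replicates and from 0.698 to 0.759 between groups.

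The first question was how far EPA alone lowered the signal. Cells without siRNA read 51380 ± 758 units untreated and 25690 ± 2841 with EPA (SD, n = 3 each), so 50.0% ± 3.22 (SE) of the signal was left. OTP3, the negative control siRNA, read 49200 ± 1292 and 24970 ± 2908, or 50.8% ± 3.50 left. The median over the library siRNAs fell from 22990 ± 1184 to 13560 ± 1404, or 59.0% ± 3.94 left. After subtraction of the blank wells 46.4% of the OTP3 signal and 50.3% of the library median were left. All 3 EPA-treated samples lay below all 3 untreated samples in each of these comparisons (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

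TOX, the positive control siRNA, brought the signal close to the blank level. The median of its wells was 4539 ± 277 untreated and 3834 ± 123 with EPA, beside blank wells at a mean of 3738 ± 40.5 and 3888 ± 28.9 (SD, n = 3 each). As a mean over wells TOX stood at 12.9% ± 7.08 of OTP3 untreated and at 16.03% ± 0.734 with EPA, with the samples of the groups overlapping (exact permutation p = 0.4). The untreated mean holds 3 wells on plate 3 of untreated replicate 1 that read 46740 to 51673. Leaving out untreated replicate 1 lowered that share to 8.76%. As a median over wells the share was 9.25% ± 0.763 untreated and 17.8% ± 2.55 with EPA, and all 3 EPA-treated samples lay above all 3 untreated samples (exact permutation p = 0.1). After blank subtraction the mean share was 14.5% in untreated replicate 1, which holds the 3 wells, 1.28% and 1.21% in the others, and 1.83%, -0.28% and -0.452% with EPA, so the groups overlapped (exact permutation p = 0.3). The Z′ factor of OTP3 against TOX had a median of 0.493 over the 9 untreated plates and of -0.85 over the 9 EPA-treated plates.

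EPA acted unevenly over the plates. In wells of cells alone, 92.1% ± 2.97 (SE) of the signal was left in plate row 1 and 80.4% ± 4.05 in row 16, but 31.4% ± 2.02 in row 9. OTP3 wells showed the same course, with 84.6% ± 3.36 left in row 1 and 35.1% ± 2.05 in row 9. The coefficient of variation between OTP3 wells was 16.9% ± 0.656 untreated and 52.4% ± 5.74 with EPA (SD, n = 3). Of the library wells, 159 (16.9%) lay in rows 1 and 16 or column 24, called edge wells here.

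**Figure D1:**
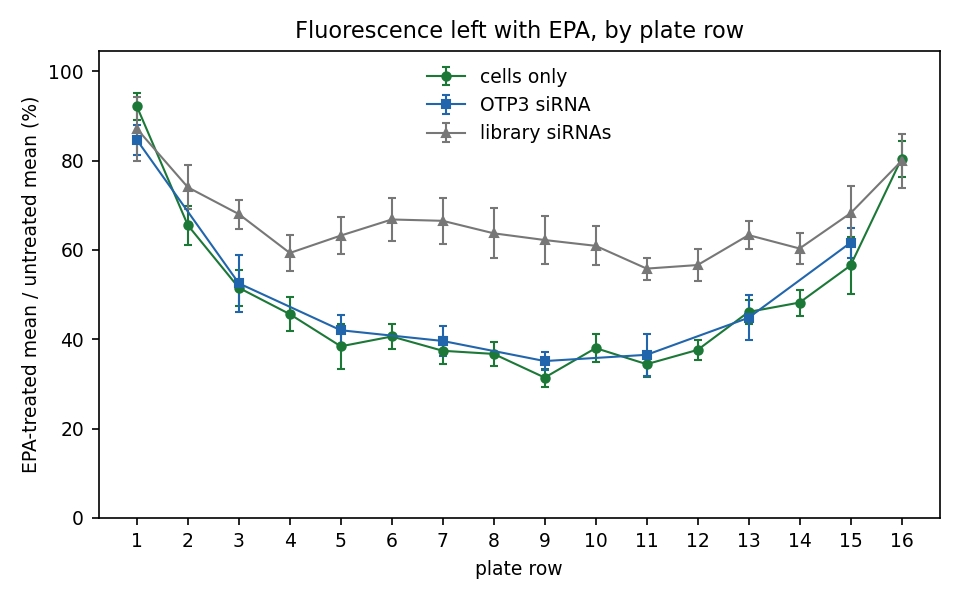
Fluorescence left with EPA, as the mean of 3 EPA-treated samples in percent of the mean of 3 untreated samples, by plate row, for wells of cells alone, OTP3 wells and library wells; bars are the SE of the ratio. Cells alone kept 92.1% in row 1 and 31.4% in row 9.

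The second question was which siRNAs changed the signal without EPA. The siRNAs against PLK1, a kinase of mitosis, and JAK2, a cytokine receptor kinase, gave the lowest signal, at -2.69 and -2.67 log2 units from the library median (SE 0.0947 and 0.0981). Their wells read 3805 ± 151 and 3856 ± 352 (SD, n = 3), the level of blank wells. CHEK1 (-2.38), TTK (-2.12) and WEE1 (-2.02), kinases of the cell cycle and its checkpoints, followed, with the coat protein gene COPB2 (-2.30), FN3KRP (-2.20), SMG1 (-2.19), CCL17 (-2.19), TRAT1 (-2.11, listed in the file as TRIM), ADCK5 (-2.07) and PIK3C2A (-1.98). All 12 were below the library median in 3 of 3 samples, with adjusted p between 2.22e-08 and 1.57e-07. The highest signals came from EDNRA (1.72), GPR183 (1.62, listed as EBI2), RIPK3 (1.36), CILK1 (1.32, listed as ICK), BMPR1B (1.30), CXCL3 (1.28), CHRM1 (1.28) and TEK (1.27), and all 8 sat in edge wells. After median polish all 12 lowest still passed, but with SMG1 at -1.04, TTK at -1.14, ADCK5 at -1.15, CCL17 at -1.30 and FN3KRP at -0.905. Of the 8 highest 7 still passed there, between 0.52 (CXCL3 and TEK) and 1.04 (EDNRA), and BMPR1B (0.075) did not. In limma's test 334 siRNAs were lower and 318 higher than the library median at an adjusted p under 0.05. Edge wells made up 4.79% of the lower and 34.6% of the higher calls, against 16.9% of all library wells (Fisher's exact p = 2.31e-15 and 1.17e-23). These are relative calls, since the library median was itself 46.7% ± 2.51 of OTP3. Centred on OTP3, which moved the median siRNA to -1.11, 868 were lower and 8 higher, and with blank subtraction and median polish together 219 were lower.

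Mitotic kinases had 11 members lower and 7 higher among 23 measured, led by PLK1, CHEK1, TTK and WEE1, and 12 lower and 2 higher after median polish. Casein kinases and GSK3 had 5 lower and 4 higher among 12 (11 and 0 when centred on OTP3), with CSNK2A2 at -1.79, CSNK1G1 at -1.68, CSNK2B at -1.35 and GSK3B at 1.08. AMPK, LKB1 and their relatives had 10 lower and 4 higher among 16, with PRKAG3 at -1.56 and STK11, the gene for LKB1, at -1.18. After median polish that list had 3 lower and 2 higher. TGF-beta and BMP receptors had 0 lower and 9 higher among 12, among them BMPR1B and BMPR1A (0.86). After median polish 3 were higher, without BMPR1A and BMPR1B, which no longer passed. Of the 4 JAK kinases JAK2 was lower, JAK1 (0.53) and TYK2 (0.77) were higher, and JAK3 was at 0.07 (adjusted p = 0.718). Centred on OTP3, 8 TGF-beta and BMP receptors were lower and 1 higher, and all 4 JAK kinases and all 23 mitotic kinases were lower. The higher calls in these lists are therefore relative to the library. The counts of these lists were the same when adjusted over the list alone. By camera 0 of the 26 lists differed from the other siRNAs at an adjusted p under 0.05 (lowest for TGF-beta and BMP receptors, 0.125, and 0.916 with an estimated correlation), and 4 had an unadjusted p under 0.05. The fry test, which asks only whether the average effect of a list's own members differs from 0, called 20. Members of such a list need not move one way, as casein kinases and GSK3, with 5 lower and 4 higher, were among the 20.

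With EPA, 5 of the 12 lowest siRNAs were the same as without it. JAK2 was at -2.02 (SE 0.0981), PLK1 at -1.99 (SE 0.0947), FN3KRP at -1.87, CHEK1 at -1.75 and ADCK5 at -1.74, and CDK10 (-1.83), CD4 (-1.80), PPP2CB (-1.75), MAST3 (-1.71) and DGKZ (-1.69) were also among the 12. After median polish these 10 still passed, but FN3KRP stood at -0.31, DGKZ at -0.45, CDK10 at -0.51, CD4 at -0.75 and ADCK5 at -0.795. With EPA the wells of these 10 read from 3647 (JAK2) to 4645 (DGKZ), close to blank wells at 3888, so their order and the size of their values are limited by the blank level. PI4K2A (-1.81, listed as PI4KII), a phosphatidylinositol 4-kinase, was among the 12 with EPA and stood at 0.05 without it. The highest were GPR183 (2.28), TAF1L (2.15), BMPR1B (1.99), TAF1 (1.98), IL2 (1.95), RASGRF2 (1.95), RIPK2 (1.90) and MAP3K5 (1.90), and all 8 sat in edge wells. After median polish BMPR1B stood at -0.10, RASGRF2 at 0.08 and IL2 at 0.26, and none of these 3 passed; the other 5 did, with MAP3K5 at 0.43. In limma's test 347 siRNAs were lower and 342 higher (687 and 105 when centred on OTP3). Edge wells made up 3.17% of the 347 and 36.8% of the 342, against 16.9% of all library wells (Fisher's exact p = 3.53e-21 and 5.12e-34). EIF2AK1 to EIF2AK4 and ERN1, the kinases of the integrated stress response and the unfolded protein response, were all higher, 5 of 5 measured, also when adjusted over the list alone, with EIF2AK2 at 1.33 and EIF2AK1 at 0.88. Without EPA 4 of the 5 were already higher (list median 0.75, and 0.70 with EPA), and ERN1 was not; centred on OTP3, with EPA 1 was lower and 1 higher. After median polish 4 were higher, with EIF2AK1 at 0.43, and ERN1 (0.05) no longer passed. JNK and p38 stress kinases had 4 lower and 16 higher among 25 (4 and 15 without EPA), also when adjusted over the list alone (11 and 8 when centred on OTP3, 6 and 14 after median polish), with MAP3K5 and MAP3K4 (1.63) in edge wells. By camera 0 lists passed (lowest adjusted p 0.0986, and 0.808 with an estimated correlation), 3 had an unadjusted p under 0.05, and fry called 20.

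Of the siRNAs, 236 were lower in both groups, where independent lists of these sizes would share 123, and 238 were higher in both, where they would share 116. The log2 values of the groups correlated at Pearson r = 0.763 and Spearman rho = 0.751 across siRNAs. No sample was shared between the groups, but each siRNA had the same plate position in both. A further 28 siRNAs were higher than the library median without EPA and lower with it, and 4 were the reverse.

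The third comparison, EPA-treated minus untreated, is the synthetic lethal one. The siRNA against FLT1, a receptor of vascular endothelial growth factor, was at -2.01 (SE 0.188, adjusted p = 0.000169), its wells falling from 30600 ± 7258 to 4667 ± 516 (SD, n = 3). PI4K2A and PFKL, the liver form of phosphofructokinase, were both at -1.85, their wells reading 4211 ± 210 and 5077 ± 555 with EPA. These 3 came close to the blank level with EPA, so the size of their values depends on the background: after blank subtraction FLT1 was at -4.36, PI4K2A at -4.19 and PFKL at -3.65. EPHA2, an Eph receptor tyrosine kinase, was at -1.63 (SE 0.159, adjusted p = 0.000169). Its wells read 44690 ± 2207 untreated, 0.89 above the library median, and 8966 ± 640 with EPA, -0.75 from it, so 20.1% of the signal was left where OTP3 kept 50.8%. After blank subtraction the EPHA2 difference was -2.14. After median polish EPHA2 stood at 0.24 untreated, no longer past the threshold (limma adjusted p = 0.184), and at -1.25 with EPA. Among the lowest were also DCLK1 (-1.75, listed as DCAMKL1), TNNI3K (-1.75), AMHR2 (-1.67), LPAR1 (-1.62, listed as EDG2), DUSP4 (-1.61), STK10 (-1.60) and MOS (-1.57). None of these 11 sat in an edge well, and for all 11 the 3 EPA-treated values lay below the 3 untreated values. After median polish all 11 still passed, between -1.83 (PI4K2A) and -1.06 (MOS).

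In limma's test 143 siRNAs were lower with EPA and 272 higher. With a log2 difference beyond 1 there were 46 lower and 10 higher. On the log2 scale of the fit the groups did not overlap for 515 siRNAs (54.8%, where chance gives 10%). The excess of higher calls depended on the centring. The median siRNA stood at 0.20, and centred on that median per plate 194 were lower and 131 higher, with all 143 lower calls kept. Median polish gave 139 lower and 153 higher, quantile normalization 148 and 158, blank subtraction with median polish 146 and 129, and OTP3 centring 91 and 437. Of the original calls, 93 of 143 lower and 75 of 272 higher passed in the same direction in all 4 of the plain fit, blank subtraction, median polish and both together.

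**Figure D2:**
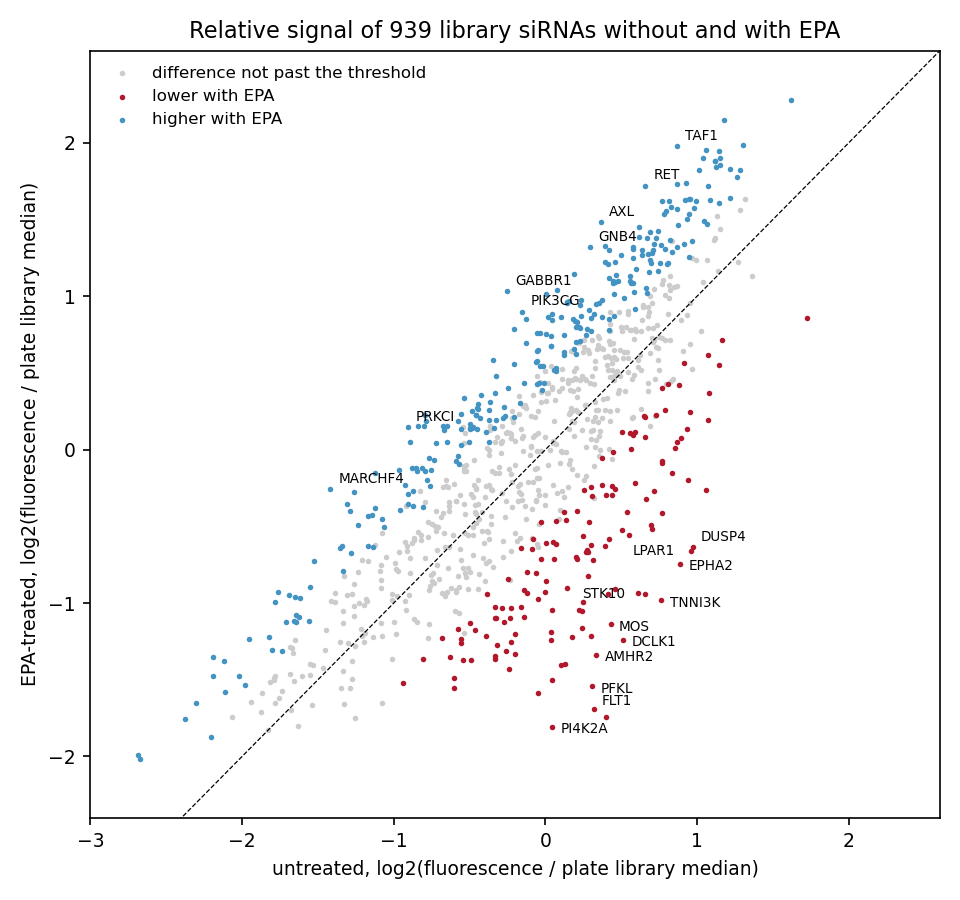
Mean log2 ratio of fluorescence to the plate's library median for 939 siRNAs, untreated on the x axis and EPA-treated on the y axis (n = 3 each); colours mark siRNAs past the threshold for EPA-treated minus untreated, and the dashed line marks equal values. The 143 lower siRNAs lie below the line, with EPHA2 at 0.89 and -0.75, and the 272 higher siRNAs lie above it.

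The highest values were those of GABBR1 (1.29, SE 0.298), MARCHF4 (1.16, listed as KIAA1399), AXL (1.12), TAF1 (1.11), RET (1.07), PRKCI (1.06), PIK3CG (1.05) and GNB4 (1.03). AXL, TAF1, RET and GNB4 sat in edge wells. After median polish AXL stood at 0.28 and GNB4 at 0.19 and no longer passed. The other 6 still passed, but RET, at 0.49 there, did not pass with blank subtraction too (0.35). PLK1 (0.70) and JAK2 (0.66), named here after their values were seen, were also called higher, with wells at the blank level in both groups (3707 ± 143 and 3647 ± 28.4 with EPA), where no further loss of signal can be read. Neither passed after blank subtraction alone, and both did after median polish. Of the 272 higher calls 32 had an untreated mean under 2 times the untreated TOX median, taken here over all wells and samples together (a cut of 8828). Of the 143 lower calls 0 had.

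**Figure D3:**
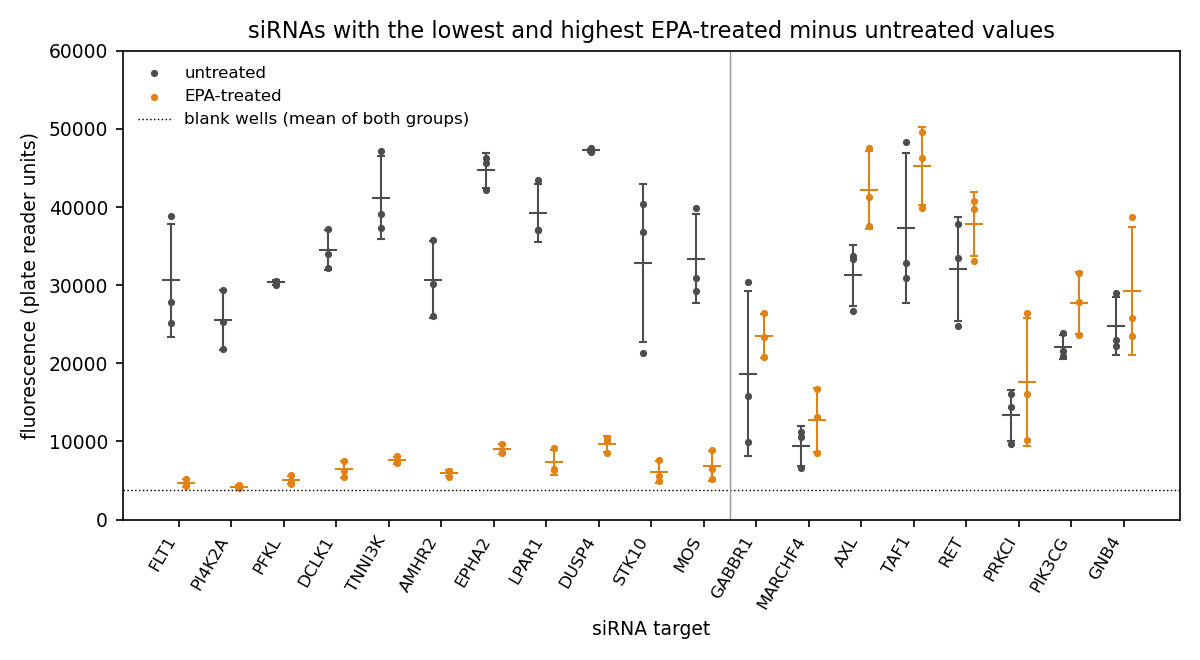
Fluorescence of each sample for 11 of the lowest (left of the grey line) and the 8 highest siRNAs by EPA-treated minus untreated value; dots are samples, bars the mean and SD (n = 3), and the dotted line the mean of the blank wells. EPHA2 wells had means of 44690 untreated and 8966 with EPA. Values shown are raw, while absence of overlap was judged on log2 values relative to the plate's library median. Raw values of the highest siRNAs can overlap, as for GABBR1 (9899 to 30379 untreated, 20773 to 26394 with EPA).

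By gene group, 13 Eph receptors were measured. EPHA2 was lower with EPA and 5 were higher (1 and 6 adjusted over the list alone), among them EPHB1 at 0.75, EPHB2 at 0.61 and EPHA8 at 0.59, and 10 of the 13 sat in edge wells. After median polish EPHA2 stood at -1.495 (adjusted p = 6.59e-05, with 6.49e-05 to 0.00174 over 21 alternatives). EPHB4 was lower there too, at -0.81, and 1 receptor, EPHA6 at 0.97, was higher. The 10 edge wells shared row 16 of plate 1, so median polish can remove an effect common to them along with that of the row. EPHA6 wells gave a low signal, 6234 ± 610 untreated and 6476 ± 1473 with EPA (SD, n = 3). EPHA6 did not pass after blank subtraction alone (0.84, limma adjusted p = 0.177) but did with both corrections. Other receptor tyrosine kinases had 5 lower and 11 higher among 36, with FLT1, AXL and RET among them, but 6 lower and 5 higher when centred on the median siRNA and 4 and 7 after median polish. Sugar and energy metabolism kinases had 8 lower and 9 higher among 32, with PFKL, the creatine kinases CKB (-1.23) and CKMT1B (-1.03) and the phosphoglycerate kinase PGK2 (-1.11) lower. After median polish that list had 9 lower and 4 higher, and 7 and 11 with OTP3 centring. SRC-family and focal adhesion kinases had 5 lower and 3 higher among 18, with PTK6 at -1.35, SRC at -1.0, ABL2 at -0.81 and ILK, in an edge well, at 0.95. With OTP3 centring 3 were lower and 5 higher, and after median polish 3 were lower and 1 higher, and ILK (0.26) no longer passed. TGF-beta and BMP receptors had 4 lower and 3 higher among 12 (3 and 4 with OTP3 centring), with AMHR2 and TGFBR2 (-0.94) lower and BMPR1A (0.86) and BMPR1B (0.69), both in edge wells, higher. After median polish BMPR1A and BMPR1B no longer passed, and that list had 3 lower and 1 higher.

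Mitotic kinases had 0 lower and 10 higher among 23, with AURKB at 0.77, TTK at 0.74 and PLK1 at 0.70, and 5 higher after blank subtraction and 9 after median polish. TTK wells (4617 untreated, 4405 with EPA) and PLK1 wells (3805 and 3707) lay near the blank level in both groups, where little further loss can be read. Neither passed after blank subtraction alone (limma adjusted p = 0.21 and 0.159), though both did after median polish. AURKB passed in each of these 2 fits. PI3K, AKT and MTOR signalling had 1 lower, MTOR at -1.54 (SE 0.197, adjusted p = 0.000549, listed as FRAP1), and 8 higher among 21, led by PIK3CG; after centring on the median siRNA 2 were lower and 2 higher, and after median polish 1 and 4. NF-kB and innate immune kinases had 0 lower and 7 higher among 13, led by MAP3K8 (0.81) and RIPK1 (0.86), with 8 of the 13 in edge wells, and 2 lower and 0 higher after median polish. Splicing-related kinases had 2 lower, DYRK1B at -1.52 and SRPK3 at -1.19, and 5 higher among 12, but 2 and 2 after median polish. Of the 2 measured kinases of the mevalonate pathway, too few to test, MVK was at -1.03 (adjusted p = 0.000909) and PMVK at -0.26 (adjusted p = 0.211). Adjusted over the list alone, sugar and energy metabolism kinases had 8 lower and 10 higher and TGF-beta and BMP receptors 5 and 3, while the other lists described after the Eph receptors kept their counts. By camera 0 lists passed (lowest adjusted p 0.559, and 0.976 with an estimated correlation), 1 had an unadjusted p under 0.05, and fry called 3: the Eph receptors, the mitotic kinases and the phosphoinositide kinases, which had 1 lower and 5 higher among 18 (3 lower and 1 higher after median polish). After median polish fry called 0 lists for this comparison. With blank subtraction too it called 3, of which only the phosphoinositide kinases were among the first 3, and their mean log2 value was then -0.21, against 0.16 before.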

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

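Of the tests in this part, the medians of the lower and of the higher siRNAs after median polish, blank subtraction together with median polish, blank subtraction split by the side of the library median, the level of the 3 TOX wells against cells alone and centring on the median siRNA were chosen only after the result was seen. EPA-treated minus untreated is itself a test of a difference between groups, and what it called is listed here. Among the lowest siRNAs were FLT1 (-2.01), PI4K2A (-1.85), PFKL (-1.85), DCLK1 (-1.75), TNNI3K (-1.75), AMHR2 (-1.67), EPHA2 (-1.63), LPAR1 (-1.62), DUSP4 (-1.61), STK10 (-1.60) and MOS (-1.57). The 8 highest were GABBR1 (1.29), MARCHF4 (1.16), AXL (1.12), TAF1 (1.11), RET (1.07), PRKCI (1.06), PIK3CG (1.05) and GNB4 (1.03). The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05; the real split, 1 of them, gave 415 calls and the highest of the others gave 0.

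The 272 siRNAs with a higher relative signal with EPA held 88 edge wells (32.4%, against 16.9% of all library wells, Fisher's exact p = 1.41e-14). After median polish 115 of them (42.3%, exact 95% interval 36.3 to 48.4) still passed in the same direction, so row and column trends may account for many of these calls. The median of all 272 was 0.643 before and 0.405 after, with quartiles of 0.219 and 0.641, which argues against trends as the whole cause. That argument is limited, since the 272 were picked on these same values and noise picked with them stays in the median. A floor at the blank level stays open for 66 of the 272. It pulls values towards the library median, so it could make a higher call only below that median with EPA. The other 206 lay above it, which argues against a floor as their cause. After blank subtraction 224 of the 272 (82.4%, interval 77.3 to 86.7) still passed. Subtraction moved none of the 206 nearer 0 (median 0.641 before and 0.847 after), so it does not test them. Of the 66 only 22 (33.3%, interval 22.2 to 46) still passed, as the median SE rose from 0.158 to 0.33 while their median value went from 0.654 to 0.745. Centring is also open, as 131 of the 272 still passed once the median siRNA was set to 0. An effect of EPA on the response to these siRNAs stays open as well, and 75 passed in all 4 of the plain fit, median polish, blank subtraction and both together. Not passing in all 4 does not exclude an effect for the others.

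The 143 siRNAs with a lower relative signal with EPA held 10 edge wells (6.99%, Fisher's exact p = 0.000258). A floor at the blank level stays open for 25 of the 143. Pulling values towards the library median, it could make a lower call only above that median with EPA. The other 118 lay below it, which argues against a floor as their cause. After blank subtraction 128 of the 143 (89.5%, interval 83.3 to 94) still passed. Subtraction moved none of the 118 nearer 0 (median -0.925 before and -1.559 after), so it does not test them. Of the 25 only 13 (52%, interval 31.3 to 72.2) still passed, with a median SE of 0.175 against 0.141 before and a median value of -0.546 against -0.504. Row and column trends as the whole cause are argued against by the median of all 143, which was -0.787 after median polish and -0.846 before, with quartiles of -1.07 and -0.44. The same limit holds, since the 143 were also picked on these values. For single siRNAs position remains open: 105 (73.4%, interval 65.4 to 80.5) still passed after median polish, and 21 of the 48 OTP3 wells (43.8%, interval 29.5 to 58.8), which all hold 1 siRNA, were themselves called against their plate's OTP3 median, 9 lower and 12 higher. An added effect of EPA stays open beside it, and 62 library siRNAs, EPHA2 among them, lay below the lowest OTP3 well (-0.892), each measured from the median of its own kind and with OTP3 in the control columns only. That sets 939 library wells against the lowest of only 48 OTP3 wells, whose SD was 0.495. Some of the 62 could lie there through spread between wells alone, and how many was not tested.

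In plate 3 of untreated replicate 1, 3 TOX wells averaged 49170 units, while the highest of the other TOX values was 8115. The cells-only wells of that plate averaged 49430, and the lowest of the 3 wells stood at 94.6% of that mean, which is consistent with no active TOX siRNA having reached them. An exchange of the whole plate is argued against by its library wells, which correlated with both other untreated replicates at r = 0.912 or more. No biological explanation was tested.

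Wells marked as holding no siRNA, which entered no fit, read 43940 ± 2673 units untreated and 17280 ± 717 with EPA (SD, n = 3), above the blank wells in both groups. With EPA 39.3% ± 1.67 (SE) of that signal was left (exact permutation p = 0.1), where cells alone kept 50.0%, but these 21 wells were all on plate 3, in rows 11, 13 and 15, so the shares are not from the same positions.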

How the results depend on the processing

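Of the alternatives here, blank subtraction with median polish, leaving out edge wells or plate 3 of untreated replicate 1, the filter on the TOX median and centring on the median siRNA were chosen only after the result was seen. The 11 named lowest siRNAs of EPA-treated minus untreated kept direction and threshold in all 231 values they had over 21 alternatives, as the 8 highest did in 159 of 164. The other 5 values, of AXL, GNB4 and RET, came after median polish, alone or with blank subtraction. These siRNAs were picked as extremes in the same data, and some alternatives, such as the looser thresholds, could not undo a call, so the shares overstate stability. OTP3 centring gave 868 lower and 8 higher siRNAs without EPA, 687 and 105 with EPA, and 91 and 437 for EPA-treated minus untreated; it sets a control in place of the library median, which is below that control, and put the median siRNA at -1.11, -0.85 and 0.44. Higher calls of EPA-treated minus untreated came to 158 with quantile normalization, 153 with median polish, 129 with blank subtraction and median polish, and 131 when centred on the median siRNA. Blank subtraction with median polish left 219 lower siRNAs without EPA. With EPA, BMPR1B reversed to -0.103 after median polish and to -0.155 with blank subtraction too, where RASGRF2 reversed to -0.043; neither passed, and the cause was not tested for any of these changes. TOX as a share of OTP3 was 5.68% untreated, a mean carried by untreated replicate 1, and 0.367% with EPA after blank subtraction, and as a median over wells 9.25% untreated and 17.8% with EPA. OTP3 centring made camera call 1 list without EPA and 2 lists with EPA, and 0 and 0 with an estimated correlation. With the library median as the centre fry, which asks another question, called 20, 20 and 3 lists, the last ranging from 0 to 13 over the alternatives.

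Leaving out 1 replicate gave 290 to 341 lower and 280 to 328 higher siRNAs without EPA, 324 to 346 and 319 to 340 with EPA, and 118 to 129 and 209 to 277 for EPA-treated minus untreated. The ratio of library medians ranged from 0.556 to 0.616, TOX as a share of OTP3 from 8.76% to 15.01% untreated and from 15.7% to 16.4% with EPA, and camera called 0 lists each time, while fry called 0 lists for EPA-treated minus untreated in 4 of the 6 fits. EPHA3 passed as higher without EPA-treated replicate 4 (0.60), as EPHA1 did without EPA-treated replicate 6 (0.60). No paired analysis was possible because the columns are numbered 1 to 6 through both groups and share no number, so the alternatives with a replicate block were not run. Signal over the blank level limits what can be read at the low end: 66 library siRNAs had an untreated mean under 2 times the pooled untreated TOX median, or 8828 units.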

Other observations

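Of the tests in this part, the comparison of reagents on 2 wells was chosen only after the result was seen. Among comparisons not described above, casein kinases and GSK3 had 2 lower and 1 higher among 12 in EPA-treated minus untreated (2 and 4 with OTP3 centring, 3 and 1 after median polish), with CSNK1G3 at -1.40 and GSK3B at -0.71. JNK and p38 stress kinases had 2 lower and 8 higher among 25 (1 and 8 adjusted over the list alone), but 4 lower and 1 higher with quantile normalization and 2 and 3 after median polish. AMPK, LKB1 and their relatives had 1 lower and 4 higher among 16, but 2 and 0 when centred on the median siRNA.

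The same reagent was present on 2 wells for 13 catalogue numbers. Within a group the values of the 2 wells differed by 3.14 times what the replicate standard errors give untreated and 3.81 times with EPA, and by 2.49 and 2.16 times after median polish, so wells differed by more than the replicates show. For EPA-treated minus untreated the root mean square difference was 0.422, or 1.49 times the 0.284 that those errors give, which neither excludes nor bears out the same hypothesis there. Across the 13 pairs Pearson's r was 0.601 untreated (permutation p = 0.03, adjusted p = 0.045 over 3 contrasts), 0.290 with EPA (p = 0.35, adjusted p = 0.35), where 1 pair had opposite calls, and 0.666 for EPA-treated minus untreated (p = 0.012, adjusted p = 0.036); Spearman's rho was 0.670, 0.242 and 0.451 (permutation p = 0.015, 0.43 and 0.12, adjusted p = 0.045, 0.43 and 0.18). Without the 2 pairs whose first well lay farthest from the median in that contrast, r was 0.393, 0.355 and 0.233. The relation in EPA-treated minus untreated may rest on those pairs. Narrowing the range of values can by itself lower r, so the drop cannot decide this. After median polish, over all 13 pairs, Pearson's r was 0.638 untreated, 0.607 with EPA and 0.679 for EPA-treated minus untreated. There 0 pairs had opposite calls with EPA.

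Plate 3 held 160 GPCR-library and 139 kinome-library siRNAs. The hypothesis that the libraries differ in EPA-treated minus untreated was not borne out, at means of 0.117 ± 0.619 and 0.137 ± 0.548 (SD, permutation p = 0.76, the larger of the values before and after median polish).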
